A study of Mus musculus with 6 samples.

How the data were processed

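Total RNA of NIH/3T3 cells, an immortalised line of mouse embryo fibroblasts, was sequenced from wild-type (WT) cells and from a pair of clones in which Mki67, the gene of the proliferation antigen Ki-67, had been knocked out. Each of the 3 groups held 2 libraries. Per the labels' protocols, RNA was depleted of ribosomal RNA and made into libraries with a strand-specific total RNA kit. That protocol text names knockout lines of 4T1, a mouse mammary tumour line, whereas the titles, sources and tissue labels of the same samples name NIH/3T3 fibroblasts. Samples were taken as NIH/3T3 from the latter, and epithelial and mesenchymal marker levels were set beside that choice. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The way the clones were made, their passage and the edited part of the gene are not given in the sources used here.

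Per the submitters' processing notes, read quality was viewed with FastQC and reads were aligned with STAR 2.6.0c to GRCm38. The deposited values are raw read counts per Ensembl gene, in the layout of STAR's own gene counting, with a column that ignores strand and 1 for each strand. The annotation release used for counting is not given in the sources used here. The reverse-strand counts were used, since the kit marks strand in that way. Reads on the opposite strand made up 4.68% to 6.10% of the counts of both strands. The rows that name no gene held 46.6% to 50.5% of the reads in each library and stayed out of library sizes and tests. Among them, multimapping reads took 28.3% to 30.3% of the reads and unmapped reads 6.10% to 9.68%. STAR leaves reads with several hits and reads over overlapping genes out of the gene counts, so genes with near-identical copies, such as Tmsb4x, H2-K1, the Trim30 family and ribosomal protein genes, are measured by their unique parts and are uncertain.

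Gene symbols, biotypes and positions were taken from a GENCODE M21 annotation of GRCm38, which matched 54079 of 54146 gene identifiers. Gene counts summed to 3873249 and 11377172 for WT replicates 1 and 2, 19678782 and 15491116 for clone 1, and 15862850 and 15087148 for clone 2. A floor of 3 counts corresponds to 0.775 CPM (counts scaled to the library total) in the shallowest library and 0.152 CPM in the deepest. Intervals and floors cover counting error only. Replicates within a group differed by more than sampling noise, with chi-square values per degree of freedom of 13.6 in WT, 19.6 in clone 1 and 22.3 in clone 2.

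Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, counts were scaled by TMM (factors 0.951 to 1.03), and a quasi-likelihood model with 1 coefficient per group was fitted to all 6 libraries, leaving 3 residual degrees of freedom. The contrasts were the mean of both clones against WT, each clone against WT, and clone 2 against clone 1. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Adjusted p-values of genes below come from edgeR's quasi-likelihood test. Log2 fold changes are given with their standard error (SE) and CPM values as mean ± SD of 2 libraries. Where a group had 0 counts, a fold is a lower bound against 3 counts over the group; with 1 to 3 counts, the ratio of CPM is given with its 95% counting interval. The 36 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Beside each called list stands the adjusted p with an estimated correlation, at which 0 of the 36 lists passed in any contrast. The lists for cholesterol biosynthesis, oxidative stress, xenobiotic metabolism, antigen presentation, interferon-stimulated genes, mesenchymal transition and the Notch pathway were written knowing the group's published work on Ki-67, so their direction is not independent evidence.

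Before the data were examined, the design, the lists, most of the other settings and the rule for named genes were fixed. The rule names Mki67, and then the 12 largest rises and the 12 largest falls among protein-coding genes called in both clones in the same direction with an average log2 CPM of at least 3. It adds the 8 largest in each direction between clones, up to 2 members in each direction of each list discussed, and the markers Epcam, Krt8, Col1a1, Cdkn2a and Ccnd1. Other genes named were chosen after their values were seen, and 1 list member that the rule names is not reported here. The calls shared by both clones were set beside 50 simulations of unchanged clones, since both contrasts share the WT libraries, and beside the overlap of independent lists. Each simulation drew all 6 libraries anew, WT included, at each gene's mean over the 6 libraries and its spread within groups. Both simulated clones were compared with the same simulated WT libraries.

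The steps were tested on simulated counts for 13120 genes, 200 of them changed. The test of the mean contrast recovered 37.3% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 90.9% of those changed 4-fold, with 5.30% false calls. For clone 2 against clone 1 the shares were 28.4%, 85.1% and 97.0%, with 6.67% false calls. False calls made up 3.70% of the calls for clone 1 against WT and 9.66% for clone 2 against WT. Each of these shares rests on 1 simulated data set. The other settings fixed beforehand were other size factors, no scaling, no low-count filter or a stricter filter, unstranded counts, and a replicate block. Further ones were a minimum fold of 1.5, each library left out in turn, fits of fewer libraries or groups, limma-voom, DESeq2 1.42.0, and for lists fry and an estimated correlation. Added after seeing the data were thinning to equal depth, leaving out ribosomal and small RNA genes, a correction for GC content and length, and removal of a running median over 101 neighbouring genes along each chromosome. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.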

Results

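Transcript levels were measured by strand-specific total RNA sequencing in WT cells and in 2 Mki67 knockout clones, with 2 libraries per group, all labelled by title and source as NIH/3T3 fibroblasts. Gene counts per library ranged from 3873249 in WT replicate 1 to 19678782 in clone 1 replicate 1. Across genes, log2 CPM values correlated at 0.980 between the WT libraries and at 0.993 within each clone. They correlated at 0.983 to 0.985 between clones and at 0.930 to 0.954 between WT and knockout libraries; genes are not independent replicates. The first principal component held 67.9% of the variance and the next held 13.8%. Of 13120 genes tested, 4561 were called between the mean of both clones and WT.

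Mki67, which encodes the Ki-67 protein of proliferating cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361 in GRCm38, minus strand), was lower in each knockout library than in each WT library. Its level was 49.2 and 55.2 CPM in the WT libraries, 4.24 and 4.59 CPM in clone 1, and 4.32 and 7.69 CPM in clone 2. The log2 fold change was −3.57 in clone 1 and −3.13 in clone 2, and −3.35 ± 0.18 for their mean (edgeR quasi-likelihood adjusted p = 1.13e-08). The clones did not differ detectably (log2 difference 0.44, adjusted p = 0.433). Mki67 transcripts remained countable in every knockout library; which part of the gene was edited is not given in the sources used here.

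**Figure D1:**
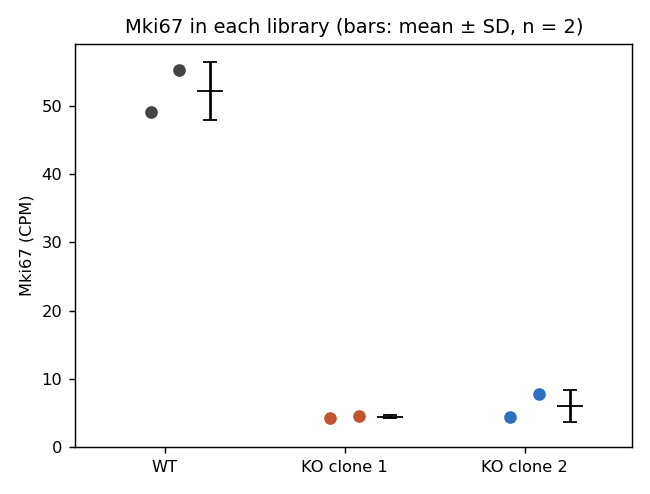
Mki67 level in CPM for each of the 6 libraries, grouped as WT, clone 1 and clone 2. WT libraries lie at 49.2 and 55.2 CPM and the 4 knockout libraries between 4.24 and 7.69 CPM.

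The epithelial and cell cycle markers fixed beforehand gave the following levels in the same libraries. Epcam, an epithelial adhesion molecule, and Cdkn2a, the Ink4a/Arf gene that NIH/3T3 cells are known to lack, had 0 counts in all 6 libraries, and the epithelial keratin gene Krt8 reached at most 0.505 CPM. The keratin gene Krt18 reached at most 0.152 CPM and the E-cadherin gene Cdh1 at most 0.543 CPM, while the collagen gene Col1a2 ranged from 1291 to 2158 CPM and the mesenchymal filament gene Vim from 3355 to 5399 CPM. These levels go with the fibroblast labels and against 4T1, the epithelial tumour line that the protocol text names, as the source of the libraries. Col1a1, the fibroblast collagen gene, ranged from 287 to 641 CPM and rose by 0.75 ± 0.13 on the log2 scale in the knockout mean. Ccnd1, the gene of cyclin D1 on chromosome 7, changed by −0.38 ± 0.11 (adjusted p = 0.0188). That call was lost without WT replicate 2 (−0.30, adjusted p = 0.0830), without clone 1 replicate 2 (−0.37, adjusted p = 0.0613), without clone 2 replicate 2 (−0.33, adjusted p = 0.0971), in a fit of 2 groups (−0.38, adjusted p = 0.0597) and after removal of the chromosome position trend.

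The comparison of knockout with WT asks which transcripts differ in cells without Ki-67. In the mean of both clones the transmembrane glycoprotein gene Emb, the cytoskeletal regulator gene Crmp1 and the matrix glycoprotein gene Tnc were among the 12 largest falls, while the calcium-stimulated adenylyl cyclase gene Adcy1 and the chitinase-like gene Chil1 rose. Tnc (chromosome 4, 63959785 to 64047015) fell from 493 ± 9.45 CPM in WT to 17.7 ± 0.789 CPM in clone 1 and 17.6 ± 0.0823 CPM in clone 2, a log2 fold change of −4.80 ± 0.11 (adjusted p = 1.79e-12). Adcy1 (chromosome 11, 7063489 to 7178506) rose from 1.81 ± 0.900 CPM to 71.9 ± 3.03 and 91.8 ± 0.677 CPM, a log2 fold change of 5.73 ± 0.22 (adjusted p = 6.63e-10). In all, 2176 genes were called higher and 2385 lower, 34.8% of those tested, and 545 and 725 of them changed at least 2-fold.

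Among the 12 largest rises, Chil1 had 0 counts in WT and was at least 52.2-fold higher in the knockout libraries. Trim30a, a member of the TRIM family, had 2 counts in WT, and its ratio was 77.9 (95% counting interval 21.5 to 644). The cardiac troponin gene Tnnt2 rose by 3.25 ± 0.18, the annexin gene Anxa8 by 3.19 ± 0.25, the autophagy receptor gene Optn by 2.95 ± 0.22 and the extracellular superoxide dismutase gene Sod3 by 2.90 ± 0.21 on the log2 scale. The remaining rises were those of the phospholipase gene Plb1 (2.78), the bone morphogenetic protein family gene Gdf5 (2.68), the chemokine gene Cxcl5 (2.65), the anchoring fibril collagen gene Col7a1 (2.39) and the cathepsin gene Ctsw (2.20). Cxcl5 rose from 6.56 ± 2.26 CPM in WT to 25.1 ± 2.72 CPM in clone 1 and 56.6 ± 0.0535 CPM in clone 2.

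Emb (chromosome 13, 117208536 to 117274415) had 32.3 ± 9.56 CPM in WT and 0 counts in all 4 knockout libraries, so that it was at least 800-fold lower. Crmp1 had 54.1 ± 3.73 CPM in WT and 3 counts in the knockout libraries together, a WT-to-knockout ratio of 1184 (95% counting interval 404 to 5752). The metalloprotease gene Adam12 (chromosome 7, 133883199 to 134232146) had 30.3 ± 2.45 CPM in WT, 4.37 ± 0.673 CPM in clone 1 and 0 counts in clone 2, where it was at least 310-fold lower than in WT. The folate enzyme gene Aldh1l1 fell to a log2 fold change of −6.81 ± 0.20, the secreted collagen triple helix protein gene Cthrc1 to −4.79 ± 0.16, Brinp3 to −4.21 ± 0.22 and the teneurin gene Tenm4 to −3.75 ± 0.18. Igf2r, the mannose 6-phosphate receptor gene, reached −3.31 ± 0.22, the actin-monomer-binding thymosin gene Tmsb4x −3.23 ± 0.10, and the Arf GTPase regulator gene Agap2 −2.91 ± 0.15. Tmsb4x fell from 725 ± 32.2 CPM to 134 ± 2.67 CPM in clone 1 and 44.1 ± 2.73 CPM in clone 2.

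Extracellular matrix genes were lower on balance, with some members rising. Of 22 tested members of the fibrillar matrix list, 6 rose and 11 fell (7 and 12 adjusted over the list alone), with a median log2 fold change of −0.44 (camera adjusted p = 1.20e-04; adjusted p = 0.777 with an estimated correlation). Setting its 3 members with 0 to 3 counts in a group at their bounds or ratios left the median at −0.44. Fmod, a small leucine-rich proteoglycan gene, rose from 2 counts in WT (ratio 51.6, 95% counting interval 14.2 to 427), and the thrombospondin gene Thbs1 rose by 1.30 ± 0.13. The collagen gene Col11a1 and the decorin gene Dcn fell to 2 counts each in the knockout libraries, with WT-to-knockout ratios of 241 (interval 65.2 to 2018) and 216 (interval 58.2 to 1812). Of 14 basement membrane genes, 2 rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.00739; adjusted p = 0.777 with an estimated correlation). The basement membrane list missed the threshold in clone 1 against WT (camera adjusted p = 0.0529) and passed it in clone 2 (0.00306). The laminin genes Lama2 and Lama4 fell to log2 fold changes of −7.09 ± 0.45 and −3.63 ± 0.25. The rise of Lama5 (0.86 ± 0.27) came to 0.44 with unstranded counts, where it was not called (adjusted p = 0.129), nor was it without clone 1 replicate 2 (0.72, adjusted p = 0.0590) or clone 2 replicate 1 (0.80, adjusted p = 0.0607). The rise of the collagen gene Col4a6 (0.39 ± 0.14) was not called in 5 of the 6 fits that left out 1 library (all but that without WT replicate 2), at values of 0.30 to 0.42. Without WT replicate 2 the basement membrane list missed the threshold (adjusted p = 0.0623), and without a low-count filter both matrix lists did (adjusted p = 0.120 for fibrillar matrix and 0.0705 for basement membrane), as with limma-voom (0.0815 and 0.0762) and fry (0.0820 and 0.0912). Among 17 matrix proteases and inhibitors, 4 rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.316), including rises of the aggrecanase gene Adamts5 by 1.47 ± 0.17 and of the inhibitor gene Timp3 by 1.11 ± 0.20.

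Stress-response and growth-factor-response genes also fell on balance. Of 19 tested genes of the integrated and ER stress list, 2 rose and 12 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.20e-04; adjusted p = 0.582 with an estimated correlation). The pseudokinase gene Trib3 and the CHOP gene Ddit3 fell to −1.80 ± 0.15 and −1.49 ± 0.14, whereas the ER chaperone genes Hsp90b1 and Hspa5 rose by 0.82 ± 0.18 and 0.65 ± 0.16. Of 18 immediate early genes, 2 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.00514; adjusted p = 0.515 with an estimated correlation). The falls were fewer in clone 2. Clone 1 had 3 higher and 10 lower members (camera adjusted p = 0.00133, and 0.479 with an estimated correlation). Clone 2 had 2 higher and 5 lower members (camera adjusted p = 0.0356, and 0.563 with an estimated correlation), and 4 members were called lower in both clones. The transcription factor genes Egr2 and Fosb fell to −2.39 ± 0.20 and −1.60 ± 0.22, and Ier3 rose by 0.96 ± 0.14. The rise of Klf6 (0.52 ± 0.15) was not called without clone 1 replicate 2 (0.38, adjusted p = 0.0510) or after correction for GC content and length (0.22, adjusted p = 0.194). The immediate early list was not called after correction for GC content and length (adjusted p = 0.138) or in a fit of 2 groups (adjusted p = 0.108).

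Mitotic genes rose as a list, while replication genes did not pass as a list. Of 30 mitosis and G2/M genes, 13 rose and 3 fell (15 and 3 adjusted over the list alone), with a median log2 fold change of 0.34 (camera adjusted p = 0.00511; adjusted p = 0.515 with an estimated correlation). Ckap2l, a spindle protein gene, rose by 1.36 ± 0.20 and the spindle checkpoint kinase gene Bub1 by 1.30 ± 0.19. The cyclin B1 gene Ccnb1 (−0.39 ± 0.12) and the anaphase activator gene Cdc20 (−0.37 ± 0.13) were called lower. Ccnb1 lost its call without WT replicate 2, clone 1 replicate 2 or either clone 2 library, at values of −0.41 to −0.36. Cdc20 lost its call without WT replicate 1, clone 1 replicate 2 or either clone 2 library, at values of −0.41 to −0.17. Of 28 DNA replication and G1/S genes, 5 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.481), the polymerase gene Pola1 rising by 1.08 ± 0.18 and the licensing factor gene Cdt1 falling to −0.58 ± 0.13. Among 15 G1 regulators, 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.881), with Cdk6 at 0.89 ± 0.16 and Cdk4 at −0.75 ± 0.12. Among 19 p53 targets, 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.622), with the sestrin gene Sesn2 at −1.03 ± 0.11. The growth factor gene Gdf15, at −1.63 ± 0.54, lost its call in 5 of the 6 fits that left out 1 library (all but that without clone 1 replicate 1), at values of −2.03 to −1.45.

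For 7 pathways the lists were written knowing the group's published work, so their direction is not independent evidence. Of 20 cholesterol biosynthesis genes, 1 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.0150; adjusted p = 0.582 with an estimated correlation). The sterol reductase gene Dhcr7, on chromosome 7, fell to −1.20 ± 0.12. Sc5d was at 0.41 ± 0.14 and came to 0.12 after correction for GC content and length, where it was not called (adjusted p = 0.348). It also lost its call without WT replicate 1 (0.23, adjusted p = 0.231), clone 1 replicate 2 (0.36, adjusted p = 0.0895) or clone 2 replicate 1 (0.36, adjusted p = 0.113). Of 10 xenobiotic genes, 4 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00641; adjusted p = 0.515 with an estimated correlation). They were led by the aryl hydrocarbon receptor gene Ahr at 4.59 ± 0.39 and the aldehyde dehydrogenase gene Aldh3a1 at 2.49 ± 0.47. The xenobiotic list missed the threshold without WT replicate 2 (adjusted p = 0.0527), clone 1 replicate 1 (adjusted p = 0.0533), clone 1 replicate 2 (adjusted p = 0.0668) or clone 2 replicate 1 (adjusted p = 0.0536), and without a low-count filter (adjusted p = 0.287). Of 23 oxidative stress and glutathione genes, 5 rose and 5 fell (camera adjusted p = 0.718). The glutathione transferase gene Gsta4 rose by 2.05 ± 0.13 and the quinone reductase gene Nqo1 by 1.39 ± 0.12, and the cystine transporter gene Slc7a11 fell to −1.68 ± 0.21. Of 14 antigen presentation genes, 3 rose and 2 fell (camera adjusted p = 0.957), with a median of 0.07 and a mean of −0.07. The class I heavy chain gene H2-K1 fell to −1.66 ± 0.12 and the tapasin gene Tapbp rose by 0.69 ± 0.11. The peptide transporter gene Tap1 (−0.42 ± 0.15) lost its call in 5 of the 6 fits that left out 1 library (all but that without clone 1 replicate 1), at −0.47 to −0.37. The disulfide isomerase gene Pdia3 (0.46 ± 0.13) lost its call without WT replicate 1 (0.33), clone 1 replicate 2 (0.40) or clone 2 replicate 1 (0.40). Of 14 interferon-stimulated genes, 1 rose and 3 fell (camera adjusted p = 0.925), with a median of 0.11 and a mean of −0.02; Ifit2 rose by 1.11 ± 0.22 and the tetherin gene Bst2 fell to −1.33 ± 0.24. Of 18 mesenchymal transition factors, 0 rose and 7 fell (camera adjusted p = 0.308), the fibronectin gene Fn1 falling to −0.83 ± 0.14 and the growth factor gene Tgfb1 to −0.73 ± 0.16. Of 10 Notch pathway genes, 1 rose and 3 fell (camera adjusted p = 0.308); the receptor gene Notch3 had 0 counts in the knockout libraries and was at least 74.4-fold lower, and Lfng, a modifier of Notch, rose by 0.90 ± 0.20. The fall of Notch1 (−0.97 ± 0.31) was not called without WT replicate 2 (−0.41, adjusted p = 0.680), clone 1 replicate 2 (−0.95, adjusted p = 0.0628) or clone 2 replicate 1 (−0.88, adjusted p = 0.0837). Counts for these last 5 lists were the same adjusted over the list alone.

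Other settings also ended calls of list members in the knockout mean. A fit of 2 groups ended those of Fmod, Lama5, Col4a6, Gdf15, Sc5d, Tap1, Notch1 and Cdc20 (adjusted p = 0.0529 to 0.0960), and DESeq2 those of Lama5, Col4a6, Gdf15, Tap1, Notch1 and Notch3 (adjusted p = 0.0560 to 0.191). Correction for GC content and length ended those of Tap1 (−0.25, adjusted p = 0.152) and Cdc20 (−0.18, adjusted p = 0.176). Ccnb1, Gdf15 and Tap1 were not called without a low-count filter, Cdc20 and Tap1 without scaling, Col4a6 and Tap1 with limma-voom or thinned to equal depth, and Gdf15 with unstranded counts. Col4a6 also lost its call with a stricter filter, with the replicate block and without ribosomal and small RNA genes. A test against a minimum fold of 1.5, which asks for more than a difference, ended 56 calls of genes that the rule names. They include those of Col1a1, Fn1, Tgfb1, Ankrd1, Cdk4, Cdk6, Cdt1, Hsp90b1, Hspa5, Tapbp, Ifit2, Lfng and Taldo1 (adjusted p = 0.0581 to 0.956) and of each gene above whose call ended with a library left out.

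Among the markers of cell types, the fibroblast and skeletal muscle lists passed in the knockout mean. Of 10 fibroblast markers, 1 rose and 6 fell, also adjusted over the list alone, with a median of −0.67 that was the same with Dcn at its ratio (camera adjusted p = 1.08e-04; adjusted p = 0.582 with an estimated correlation). The progenitor marker gene Cd34, at 382 ± 11.5 CPM in WT, fell to log2 fold changes of −2.98 in clone 1 and −1.91 in clone 2. Of 4 skeletal muscle markers, 2 rose and 0 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.0123; adjusted p = 0.707 with an estimated correlation), namely Tnnt2 and the desmin gene Des, at 1.04 ± 0.18. In clone 1 the list had 3 higher and 0 lower members (camera adjusted p = 1.92e-06; adjusted p = 0.479 with an estimated correlation), and in clone 2 it had 2 higher and 2 lower, a median of −0.65 and no call (camera adjusted p = 0.355). The call in the knockout mean was lost in every fit that left out 1 library, with adjusted p from 0.0674 to 0.120. It was also lost without a low-count filter, with the replicate block, in a fit of 2 groups and with limma-voom, with adjusted p from 0.132 to 0.387. Among lists that did not pass, the keratin gene Krt7 rose by 2.46 ± 0.33 (2 epithelial markers tested, 1 higher), the macrophage receptor gene Csf1r by 2.17 ± 0.21 (4 immune markers tested, 1 higher). The endothelial sialomucin gene Emcn fell to −1.25 ± 0.15 (3 endothelial markers tested, 2 lower). The neural stem cell filament gene Nes fell to −4.56 ± 0.27 (3 neural markers tested, 1 lower), and the bone matrix gene Spp1 to −2.12 ± 0.15 (6 cartilage and bone markers tested, 1 higher and 3 lower). The camera adjusted p-values were 0.308 for epithelial, 0.308 for immune, 0.0914 for endothelial, 0.280 for neural and 0.257 for cartilage and bone markers. In clone 1 against WT the epithelial (camera adjusted p = 0.04905) and endothelial (0.0243) lists passed, though not with an estimated correlation (0.479 for each). In clone 2 against WT neither passed (camera adjusted p = 0.685 and 0.305). The endothelial list passed with a stricter filter (adjusted p = 0.0454), unstranded counts (0.0192), correction for GC content and length (0.0442), the position trend removed (0.0289) or fry (0.0425), and without clone 1 replicate 1 (0.0499). The cartilage and bone list passed with a stricter filter (0.0261), thinned to equal depth (0.0107), with fry (0.0425) and without WT replicate 1 (0.0215), the neural list with a stricter filter (0.0161) and without WT replicate 1 (0.0215), and the epithelial list with fry (0.0280). The counts adjusted over the list alone added 1 higher neural and 1 higher cartilage and bone marker. Neural markers had a median of 0.20 and a mean of −1.04, and cartilage and bone markers a median of −0.26 and a mean of 0.34.

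Each clone was also compared with WT alone, to see what did not depend on the other clone. The changes of Tnc, Emb, Crmp1, Aldh1l1 and Adcy1 were called in both clones, as were 1256 higher and 1474 lower genes in all. Clone 1 had 1988 higher and 2166 lower genes and clone 2 had 1686 and 1906, while 12 genes were called in opposite directions. Independent lists would share 255 higher and 315 lower genes. Unchanged clones simulated with a common simulated WT group shared a mean of 0.36 and at most 2 genes. The simulated spread was that within groups, so few shared calls followed from the setting. The clones' log2 fold changes correlated across genes at 0.871 (simulated 0.657), with the same sign in 83.8% of genes (simulated 69.9%). Their covariance was 0.903 (simulated 0.0580, a difference of 0.845). Over the 9075 genes with an average log2 CPM of at least 3 the observed covariance was lower, at 0.302, without a simulated value to set beside it. Both clones were set against the same WT line, and the simulation holds no difference of that line beyond the spread between replicates. Part or all of the excess may therefore come from the shared controls.

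**Figure D2:**
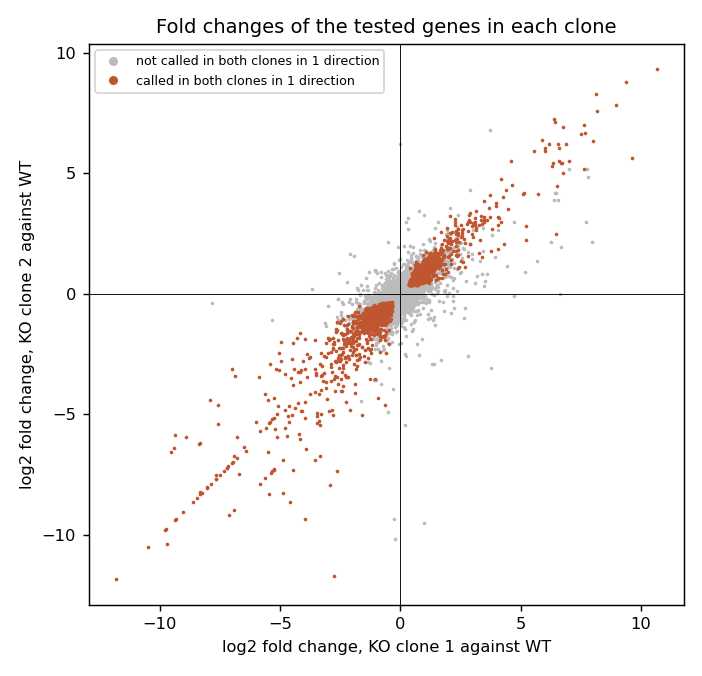
Log2 fold change against WT of each tested gene in clone 1 (horizontal axis) and clone 2 (vertical axis). The values correlate at 0.871, and 1256 higher and 1474 lower genes were called in both clones.

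Along the genome, genes of chromosomes 4, 7 and 13 were lower in both clones, a pattern singled out after the chromosome medians were seen. Over genes with an average log2 CPM of at least 3, the median log2 fold change was −0.37 on chromosome 4, −0.33 on chromosome 13 and −0.26 on chromosome 7, and 0.30 on chromosome 12. On chromosome 4 the 8 pairs of a knockout and a WT library gave medians of −0.41 to −0.33, on chromosome 13 of −0.38 to −0.19 and on chromosome 7 of −0.36 to −0.22, and replicate libraries differed by at most 0.158 in any chromosome's median. These 3 chromosomes held 17.2% of the 9062 genes, 48.4% of the 1049 genes called lower in both clones and 5.88% of the 1037 called higher. On chromosome 7, the 55 expressed genes beyond Mki67, among them Dhcr7, Taldo1 and Ccnd1, had a median of −0.64 in clone 1 and −0.59 in clone 2, against 0.09 and 0.05 for the 50 genes before it. Far from Mki67, up to position 99353239, blocks of 50 neighbouring expressed genes were also lower in the knockout mean, with medians of −0.49 to −0.17. Tnc lies on chromosome 4, Emb on chromosome 13, and Adam12 and Tenm4 on chromosome 7. After a position trend was removed along each chromosome, 1554 genes were called higher and 1914 lower in the knockout mean, and 2926 of the 4561 calls were kept; several genes named here lost their call in that contrast. Lama5 (0.77, from 0.86), Col4a6 (0.31, from 0.39) and Hspa5 (0.48, from 0.65) kept most of their log2 fold change. Ccnd1 came to −0.05, Cdc20 to −0.03, Pdia3 to 0.13, Tgfb1 to −0.31 and Ccnb1 to −0.22. In the same contrast Actg2 moved from −0.50 to −0.25, Fzd7 from 0.63 to 0.33 and Plin2 from −0.34 to −0.14, also without a call.

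**Figure D3:**
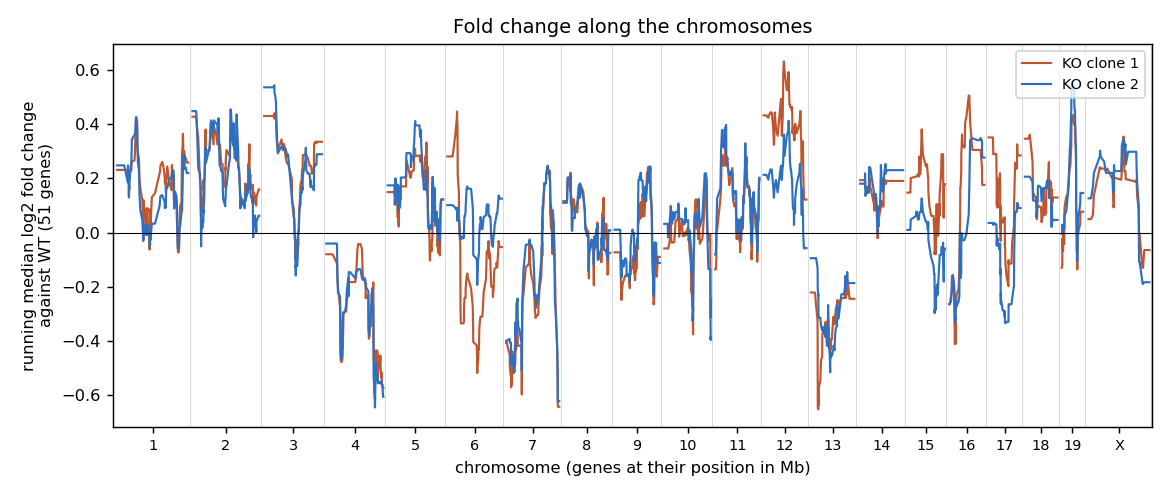
Log2 fold change of the knockout clones against WT along the chromosomes, as a running median over 51 neighbouring expressed genes, by position in GRCm38. Chromosomes 4 and 13 lie below 0 with medians of −0.37 and −0.33, and the end of chromosome 7 lies below the part just before it.

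Clone 2 was compared with clone 1 to test whether the knockout clones differed from each other. Smooth muscle genes of the contractile apparatus were lower in clone 2. The smooth muscle actin gene Acta2 (chromosome 19, 34241090 to 34255590) stood at 913 ± 154 CPM in WT, 1030 ± 11.7 CPM in clone 1 and 160 ± 7.80 CPM in clone 2. Its log2 difference between clones was −2.69 ± 0.15 (adjusted p = 1.83e-07). The actin-binding transgelin gene Tagln differed by −4.00 ± 0.28, the myosin light chain gene Myl9 by −3.40 ± 0.34 and the enteric smooth muscle actin gene Actg2 by −2.77 ± 0.17. Across the genome 155 genes were higher and 310 lower in clone 2, of which 72 and 154 differed at least 2-fold.

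Of 14 tested contractile and SRF target genes, 0 were higher and 6 lower in clone 2 (0 and 12 adjusted over the list alone; camera adjusted p = 7.11e-33; adjusted p = 0.0828 with an estimated correlation). Against WT the list was higher in clone 1 (7 higher and 2 lower; camera adjusted p = 0.0146; adjusted p = 0.561 with an estimated correlation). It was lower in clone 2 (3 higher and 5 lower; camera adjusted p = 9.00e-04; adjusted p = 0.563 with an estimated correlation). In the mean of both clones its 5 higher and 5 lower members gave a median of 0.05 and a mean of −0.24 (camera adjusted p = 0.627), with the matricellular gene Ccn1 up by 1.24 ± 0.14 and Ankrd1 by 0.98 ± 0.17. The calls of Tagln and Myl9 in the mean contrast were lost when the 4 knockout libraries formed 1 group (adjusted p = 0.195 and 0.0925).

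The other large falls from clone 1 to clone 2 were those of Adam12, which was at least 46.5-fold lower, Soga1 (−3.61 ± 0.20), Igf2r (−3.43 ± 0.32), Srpx2 (−2.44 ± 0.18) and Anxa8 (−2.25 ± 0.18). Soga1 stood at 29.6 ± 3.54 CPM in WT, 23.3 ± 1.60 CPM in clone 1 and 1.90 ± 0.0162 CPM in clone 2. The largest rises were those of Scand1 (1.98 ± 0.20), the immediate early transcription factor gene Egr1 (1.87 ± 0.15), the growth factor gene Ptn (1.43 ± 0.20) and the kinase gene Map2k6 (1.33 ± 0.16). Next came the G protein subunit gene Gng11 (1.31 ± 0.20), the pyruvate carboxylase gene Pcx (1.26 ± 0.16), Ngef (1.19 ± 0.15) and Cxcl5 (1.18 ± 0.16). Gng11 was not called when thinned to equal depth (1.18, adjusted p = 0.110). Egr1 was at 68.7 ± 11.4 CPM in WT, 16.1 ± 0.524 CPM in clone 1 and 59.1 ± 0.273 CPM in clone 2. Skeletal muscle markers were lower in clone 2 (0 higher and 3 lower of 4, or 0 and 4 adjusted over the list alone; camera adjusted p = 4.92e-18; adjusted p = 0.0828 with an estimated correlation). Mitosis and G2/M genes had a median difference of 0.18 with 0 members called in either direction, also adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.342 with an estimated correlation); without clone 2 replicate 2 that adjusted p was 0.0717. The counts of genes called between clones moved with each library left out, from 46 to 519 higher and from 110 to 689 lower.

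**Figure D4:**
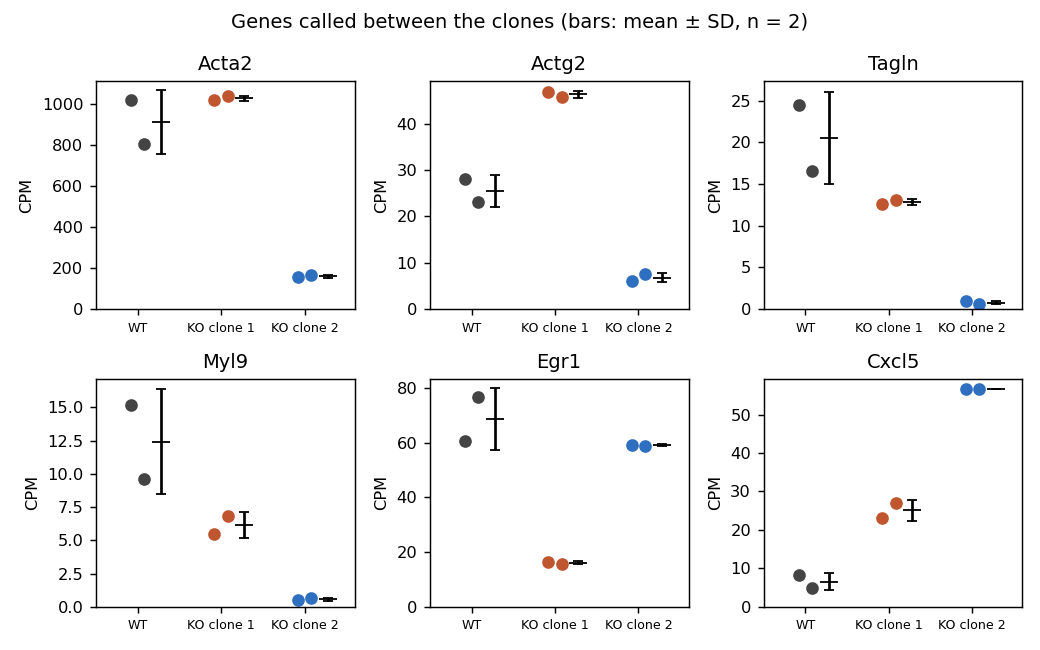
Levels in CPM of Acta2, Actg2, Tagln, Myl9, Egr1 and Cxcl5 in each of the 6 libraries, grouped as WT, clone 1 and clone 2. The 4 contractile genes are lower in clone 2 than in clone 1, and Egr1 and Cxcl5 are higher.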

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

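The test on immediate early genes below was chosen only after the result was seen. Each gene value that follows stands out because edgeR's test of the difference between the clones passed its threshold, and each list value because camera did. The levels of the 2 clones thus differed. Since each knockout is a single clone, a difference of the knockout effects cannot be told apart from other differences between the clones. Among the genes with the largest changes against WT, the log2 difference clone 2 minus clone 1 was −1.38 for Chil1, −1.08 for Tnnt2, −2.25 for Anxa8, −1.10 for Plb1, 0.81 for Gdf5 and 1.18 for Cxcl5. It was −0.59 for Col7a1, −1.25 for Ctsw, −8.91 for Adam12, 1.04 for Tenm4, −3.43 for Igf2r and −1.60 for Tmsb4x. The fitted value of Adam12 depends on the prior count, since clone 2 had 0 counts, and is no bound. Among genes named for their difference between clones it was 1.98 for Scand1, 1.87 for Egr1, 1.43 for Ptn, 1.33 for Map2k6, 1.31 for Gng11, 1.26 for Pcx, 1.19 for Ngef, −4.00 for Tagln, −3.61 for Soga1, −2.77 for Actg2, −2.69 for Acta2 and −2.44 for Srpx2. Among list members it was −0.93 for H2-K1, −3.97 for Fmod, −3.40 for Myl9, 1.06 for Egr2, −0.67 for Fzd7, 1.17 for Cxcl1, −1.07 for Ccl7, −1.90 for Krt7, 1.07 for Cd34, −0.67 for Plin2, −0.90 for Des, 1.12 for Spp1 and 0.68 for Emcn.

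Among the lists, the camera adjusted p of clone 2 against clone 1 was 7.11e-33 for contractile and SRF targets, 4.92e-18 for skeletal muscle markers, 1.09e-04 for epithelial markers, 0.0158 for mitosis and G2/M and 0.0250 for endothelial markers. With an estimated correlation none of the 5 passed, at adjusted p = 0.0828, 0.0828, 0.252, 0.342 and 0.674. The epithelial list rests on 2 tested genes, 1 of them called lower, and the endothelial list on 3, 1 of them called higher. The epithelial list did not pass without a low-count filter (adjusted p = 0.537). The endothelial list did not pass without clone 1 replicate 2 (0.185), without a low-count filter (0.142), with a stricter filter (0.0981), unstranded counts (0.0625) or fry (0.103), thinned to equal depth (0.0619) or corrected for GC content and length (0.0520). Of the contractile members called lower in clone 2, 100% kept the call after correction for GC content and length. Lower activity of SRF in clone 2 stays open. The 18 immediate early genes, some of them SRF targets, had a median log2 difference of 0.00377, with 5 called higher and 1 lower in clone 2. Camera placed the list toward higher in clone 2 (adjusted p = 0.0543, and 0.0174 to 0.479 under other settings). Among those settings the list passed as higher with DESeq2 (camera adjusted p = 0.0416) and fry (adjusted p = 0.0315), but not with an estimated correlation. A median near 0 over members that went both ways decides nothing. The rise of mitosis and G2/M genes against WT kept 71.5% of its mean log2 fold change after the same correction, and its median was 0.30 and 0.33 against the WT libraries taken alone, the lower value being 0.297.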

How the results depend on the processing

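The fits thinned to equal depth, without ribosomal and small RNA genes, corrected for GC content and length, or with the chromosome position trend removed were chosen after seeing the data; the others were planned. Where 1 library of a group was left, it was assumed to vary like the other groups. No cause of a moved value was tested except where fewer libraries or a minimum fold set it by construction. DESeq2, limma-voom, other size factors, no scaling, the stricter filter, unstranded counts and the exclusion of ribosomal and small RNA genes moved none of the counts of called genes by over 1.5 times. Without scaling, 57.2% of calls in the mean contrast were higher, against 47.7% with TMM, and the median of all genes shifted by 0.077. Of 4561 calls in the mean contrast, DESeq2 kept 3750, limma-voom 4262 and a fit of 2 groups 3487. The correction for GC content and length kept 3379 of them. Its totals of 2095 higher and 2432 lower genes were close to the 2176 and 2385 of the main fit, so part of its calls were of other genes.

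Against a minimum fold of 1.5, 330 genes were higher and 622 lower in the mean contrast, 372 and 617 in clone 1, 265 and 522 in clone 2, 28 and 92 in clone 2 against clone 1, and 566 genes changed in the same direction in both clones, 389 of them lower. For clone 2 against clone 1 (155 and 310), the counts were 264 and 549 without a low-count filter, and 55 and 161 thinned to equal depth. They were 361 and 486 corrected for GC content and length, and 96 higher with the position trend removed. With that removal 1906 genes were called in both clones, against 2730, and the number of higher ones moved by over 1.5 times, from 1256 to 825. Lists past the threshold (9 in the mean contrast and 5 between clones) fell to 0 and 0 with an estimated correlation, and between clones were 11 with DESeq2 and 8 with the position trend removed.

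With 1 library left out, the mean contrast had 1540 to 2445 higher and 1819 to 2300 lower genes, clone 1 932 to 2399 and 1273 to 2202, and clone 2 754 to 2227 and 915 to 1889. Both clones shared 1417 to 3184 genes, 590 to 1812 higher and 785 to 1479 lower, and clone 2 against clone 1 had 46 to 519 and 110 to 689. Between 7 and 10 lists passed in the mean contrast and 4 to 9 between clones. The count moved by over 1.5 times without clone 1 replicate 2 in clone 1 (932 and 1273), without clone 2 replicate 1 (754 and 915) or 2 (967 and 1116) in clone 2, and without any of the 6 libraries between clones. Between clones it was 519 and 683 without WT replicate 1 and 519 and 689 without WT replicate 2. It was 49 and 154 or 62 and 185 without clone 1 replicate 1 or 2, and 47 and 117 or 46 and 110 without clone 2 replicate 1 or 2. For genes in both clones these were clone 1 replicate 2 (1609, with 590 higher) and clone 2 replicates 1 (1417, with 632 and 785) and 2 (1755, with 800 and 955). Rpl5 was the gene whose direction turned, to −0.32 with unstranded counts (adjusted p = 0.114; 0.59 with stranded counts).

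Whether the replicate numbers pair the samples cannot be told. Over 9075 genes, deviations of same-numbered libraries correlated at 0.535 between WT and clone 1. They correlated at −0.286 between WT and clone 2 and at −0.266 between clones. Deviations were thus shared in part between groups, with the opposite sign in clone 2, and a common batch is not excluded. The replicate block gives same-numbered libraries the same term and could not take up such a pattern. With the replicate block the counts were 2443 and 2431 in the mean contrast, 2230 and 2217 in clone 1, 2001 and 1954 in clone 2, 1514 and 1516 in both (3030 together), and 232 and 402 between clones, with 8 and 5 lists. Depth limits genes near the floor of 3 counts, at 0.775 CPM in WT replicate 1; in simulated counts, 37.3% of genes changed 1.5-fold in both clones were recovered.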

Other observations

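Chosen only after the results were seen were the tests against each WT library alone, those of segments as the whole cause and of the whole of chromosomes 4, 7 and 13, and the correction for GC content and length used in several tests. Further lists fixed beforehand did not pass camera in the knockout mean, yet held called members. Of 17 HOX genes, 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.807); Hoxc5 rose by 1.49 ± 0.22 and Hoxa3 by 1.21 ± 0.22, while Hoxa10 had 0 counts in the knockout libraries and was at least 63.7-fold lower (not called with DESeq2, adjusted p = 0.146). Of 19 Polycomb genes, 5 rose and 3 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.622), among them Cbx7, a chromodomain subunit gene, at 2.45 ± 0.40, and Suz12, a core subunit gene, at 1.09 ± 0.21. Of 23 heterochromatin genes, 8 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.308), with the remodeller genes Hells at 1.19 ± 0.19 and Atrx at 1.08 ± 0.20. Of 10 chemokine and cytokine genes, 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.481; fry adjusted p = 0.0425), the chemokine gene Ccl7 falling to −2.04 ± 0.17 and the cytokine gene Il11 to −1.90 ± 0.18. Of 21 hypoxia and glycolysis genes, 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.308), with Ndrg1 at −1.13 ± 0.11 and the phosphofructokinase gene Pfkp at −1.02 ± 0.12. Of 33 cytosolic ribosomal protein genes, 1 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.157). That list passed without WT replicate 2, without a low-count filter (camera adjusted p = 0.0338) and with DESeq2 (0.0471). It also passed in clone 1 against WT (camera adjusted p = 0.0469), but not in clone 2 (0.305).

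Between clones, chromosome medians differed by 0.24 on chromosome 6, −0.19 on chromosome 17, −0.18 on chromosome 15 and −0.18 on chromosome 12 (clone 2 minus clone 1), against a largest difference between replicates of 0.158.

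Changes against WT were shared by both clones, with 320 genes changed at least 4-fold in the same direction in each. That was 38.3 times the 8.35 genes of independent lists, although both lists share the WT libraries, which by itself can make them overlap. Drift of the WT line would enter both lists, so the overlap cannot decide on independent drift of all lines as the source of the shared genes. It bears only on drift of the clones from an unchanged WT line, for which independent lists would share few genes. Drift beside a common cause stays open. Of 3181 genes called in both clones against the shallow WT replicate 1 alone, 3107 kept their direction against WT replicate 2 alone but 65.0% kept at least 50% of their log2 fold change, so that noise of the shallow library stays open as a part of the cause. GC content and length explained 8.95% of the variance over the genes called in both clones against both WT libraries and chromosome 5.68%, and 58.6% of them kept both calls and most of their change with the position trend removed, so that neither bias nor whole chromosomes nor segments may be the whole cause. Segments as a part of the cause stay open, since the correlation across genes with the 10 nearest expressed genes was 0.268. A knockout effect stays open as a hypothesis beside a difference that the WT culture or a common founder of the clones brought, because all knockout libraries were compared with a single WT line.

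The lower levels of chromosomes 4, 7 and 13 kept at least 76.4% of their medians after correction for GC content and length. They had the 3 lowest medians against WT replicate 1 alone and kept at least 83.4% of these against WT replicate 2 alone, which with the former argues against bias or noise of the shallow WT library as the cause. Medians of blocks of at least 50 neighbouring expressed genes spread from −0.584 to −0.104 on chromosome 4 and from −0.527 to −0.209 on chromosome 13, and the highest lay within the largest replicate differences of 0.239 and 0.327, so that a lower copy number of the whole cannot be told apart from one of parts. On chromosome 7 the highest block was at 0.224, beyond the largest replicate difference of 0.219, which argues against a change of the whole chromosome, although on all 3 chromosomes genes of low, middle and high expression each kept at least 68.3% of the median. DNA copy number was not analysed here, and whether the WT line gained or the clones lost copies, or whether Ki-67 bears on it, was not tested.

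Beyond Mki67, the end of chromosome 7 lay lower than the 50 genes before it by −0.65 on the log2 scale, with 8 library pairs from −0.80 to −0.51, and 36 of its 55 genes were called lower in both clones. The end of 0 of the 19 other chromosomes was lower by as much, and 88.6% of the difference was kept after correction for GC content and length. Against WT replicate 2 alone it was 78.1% of that against WT replicate 1 alone (−0.57 and −0.73), which argues against noise of the shallow library, as the former does against bias. A candidate explanation is the loss of 1 copy of the chromosome end from the edited locus on, but the step that best split the genes lay 1.41 Mb beyond Mki67 in clone 1 and 1.81 Mb before it in clone 2, next to Adam12, on opposite sides of the locus and between the distances set beforehand for and against this loss. It therefore cannot be told apart from a change with another start, or with a start of its own in each clone, since few expressed genes flank the locus. The lower level of chromosome 7 was also not confined to this end. Its blocks up to position 99353239 had medians of −0.49 to −0.17, and the 50 genes before Mki67 come from a stretch near 0.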
